A study of Arabidopsis thaliana with 6 samples.

How the data were processed

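Expression was profiled on 6 single-colour Affymetrix arrays, each hybridized with biotin-labelled RNA from Arabidopsis thaliana seedlings of the Columbia ecotype grown for 10 days, per the labels' protocols. The arrays fall into 3 genotypes with 2 arrays each. WT is the wild type. The genotype h3.3kd carries the htr4 and htr8 mutations and an artificial microRNA against HTR5, and HTR4, HTR5 and HTR8 are the genes that encode the histone variant H3.3. In h3.3kd/+ the labels give the same htr4 and htr8 mutations and write the artificial microRNA over a plus sign, the usual notation for a transgene present on one chromosome of the pair. Groups and replicate numbers were taken from the sample titles.

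The authors deposited 1 table of 22810 probe sets by 6 arrays, and every column was used. The values lie on a log2 scale, as read from their range, and the authors deposited them with 2 decimals. Affymetrix Expression Console was used to make them, per the submitters' processing notes. The summarisation method, background correction and normalization are not given in the sources used here. The 6 columns have nearly equal distributions, so scaling between arrays had been applied or the arrays were alike, and absolute shifts of the whole transcriptome cannot be read from such values. Signals near the bottom of the scale are compressed, which understates the change of dim probe sets. The table holds no detection calls, so no probe set was classed as absent, and the number of arrays limits the precision.

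The table names probe sets and not genes, and the gene table used here (TAIR10.1) holds no probe set IDs, so 0 probe sets could be paired with a locus. The 30 gene lists with 365 genes that had been fixed before the data were examined, the test of transposable element genes, the test against gene length and the per-locus collapse were therefore not run, and the signals of HTR4, HTR5 and HTR8 are not reported here, which leaves the genotype labels unchecked. The exceptions are 64 Affymetrix control probe sets, whose IDs name their target. The targets include 25S and 5S ribosomal RNA, actin, GAPDH, ubiquitin, bacterial poly-A RNAs and the hybridization controls. By design the poly-A RNAs are spiked in before labelling, but the IDs alone do not show that this was done here.

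The 22746 remaining probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in 1 model with a mean per genotype, 3 residual degrees of freedom and 4.19 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all probe sets, and an adjusted p under 0.05 counted as a change. All adjusted p-values below are from this limma model. Control probe sets were tested in the same model with all 22810 probe sets, and again with the adjustment over the 64 controls alone. Standard errors are those of the moderated model. The labels do not say that the 2 arrays of a genotype came from separate plant pools, so p-values measure the spread between these samples, which may be technical. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333 and was not used.

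Probe sets were named by a rule fixed before the data were examined. It took the largest rises and falls among called probe sets. Their mean log2 signal over the 6 arrays had to be at or above the median of 5.28. They had to target a single gene, and all 4 differences between arrays of the 2 groups had to have the same sign. As no probe set could be paired with a gene, the single-gene condition was read from an ID suffix that marks a single transcript. The rule took up to 10 per direction (up to 5 for h3.3kd against h3.3kd/+, where 4 falls and no rise passed). Because the IDs have no gene names, only the first 2 per direction and comparison are printed and the rest are given as ranges. One probe set outside the rule, 262186_at, was added after its values were seen because it was the single one called higher in h3.3kd than in h3.3kd/+.

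Both mutant genotypes were compared with the same 2 WT arrays. Values of the correlation, the covariance and the sign agreement without any change were taken from 100 simulations of unchanged groups, with each probe set's own residual variance scaled to the replicate variance of each genotype. The WT arrays could not be split into parts with 2 arrays each. The effect ratio of h3.3kd/+ to h3.3kd was the covariance of the 2 sets of log2 fold changes less the WT array variance, divided by the variance of the h3.3kd fold changes less the array variances. Its turned value divides by the corrected variance in h3.3kd/+, and the ratio of the SDs is the root of one corrected variance over the other.

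The model was tested on simulated data for h3.3kd against WT with 200 changed among 22746 probe sets. It recovered 32 of 70 changes of 0.5 log2 units, 70 of 70 changes of 1 and 60 of 60 changes of 2, and 18 calls, or 10% of the calls, were false. A simulated effect ratio of 0.7 was recovered as 0.704, and as 0.701 by the ratio of the SDs. In that simulation every h3.3kd/+ change was exactly 0.7 times the h3.3kd change. It therefore does not test these ratios where the 2 sets of changes are not proportional. Alternatives were quantile normalization again, centring each array on its median, leaving out the dimmest 40% of probe sets, a prior variance that follows the signal (trend and robust), the replicate number as a block, only the 4 arrays compared, a threshold of at least 2-fold, an adjusted p under 0.1 and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9. The deviations of same-numbered arrays from their group means correlated at 0.12, -0.02 and -0.07 between the 3 pairs of genotypes, so the replicate numbers were not treated as pairs.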

Results

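Transcript levels were measured on 6 arrays of 22810 probe sets, 2 each for WT, h3.3kd and h3.3kd/+ seedlings at 10 days. The series asks how transcription differs between wild-type plants and plants with reduced levels of the histone variant H3.3, which replaces canonical H3 in nucleosomes outside DNA replication. The median log2 signal of the arrays ranged from 5.24 to 5.34. Arrays of the same genotype correlated at r = 0.996 to 0.997 across probe sets, and the replicate SD over all probe sets was 0.157 log2 units in WT, 0.136 in h3.3kd and 0.128 in h3.3kd/+ (n = 2 each). WT arrays correlated with h3.3kd arrays at 0.988 to 0.992 and with h3.3kd/+ arrays at 0.992 to 0.993, whereas the 2 mutant genotypes correlated with each other at 0.995 to 0.996. The first principal component held 53.7% of the variance and separated WT, at -23.4 and -31.2, from h3.3kd/+ at 7.65 and 9.31 and from h3.3kd at 16.5 and 21.1. The second held 17.63% and separated h3.3kd, at 9.32 and 11.37, from h3.3kd/+ at -13.4 and -15.2, with the WT arrays apart at 11.9 and -4.01. Over the 3 genotypes together, the moderated F test of limma called 1087 probe sets. The count depended on the variance model and was 2064 with a prior variance that follows the signal.

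Among the control probe sets, the signal of 25S ribosomal RNA, the large structural RNA of the cytosolic ribosome, was lower in both mutant genotypes. It was 10.91 ± 0.21 in WT, 10.39 ± 0.04 in h3.3kd and 9.96 ± 0.05 in h3.3kd/+ (log2, SD, n = 2). The fall was 1.43-fold in h3.3kd (adjusted p = 0.0389 over all probe sets and 0.14 over the controls alone) and 1.93-fold in h3.3kd/+ (0.0127 and 0.00342). The call in h3.3kd was lost when any 1 array other than WT replicate 2 was left out (adjusted p up to 0.196), and that in h3.3kd/+ when either h3.3kd/+ array was left out (0.119 and 0.099). Between the mutants the difference of 0.43 ± 0.11 SE was not called (adjusted p = 0.345 over all probe sets and 0.193 over the controls). None of the 6 actin, 5 GAPDH and 5 ubiquitin probe sets, which target a cytoskeletal protein, a glycolytic enzyme and the protein tag of proteasomal degradation, passed the test in either mutant. Their mean log2 differences from WT were 0.0067, -0.02 and 0.004 in h3.3kd and -0.01, 0.06 and 0.03 in h3.3kd/+. Of the 24 poly-A spike-in probe sets, 0 passed in h3.3kd and 1, a dap probe set, was lower in h3.3kd/+ (-0.50 log2 units, adjusted p = 0.0399). Called or not, 6 of the 24 lay below WT in h3.3kd and 17 in h3.3kd/+, with mean differences of 0.06 and -0.11. The 18 hybridization control probe sets did not pass in either mutant. The difference between 3' and 5' probe sets of actin, GAPDH and ubiquitin, a sign of RNA integrity, averaged 1.41 ± 0.0012 in WT, 1.44 ± 0.07 in h3.3kd and 1.36 ± 0.02 in h3.3kd/+ (log2, SD, n = 2). The small WT SD comes from averaging over pairs of probe sets: single pairs had WT SDs of 0.014 to 0.148.

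**Figure D1:**
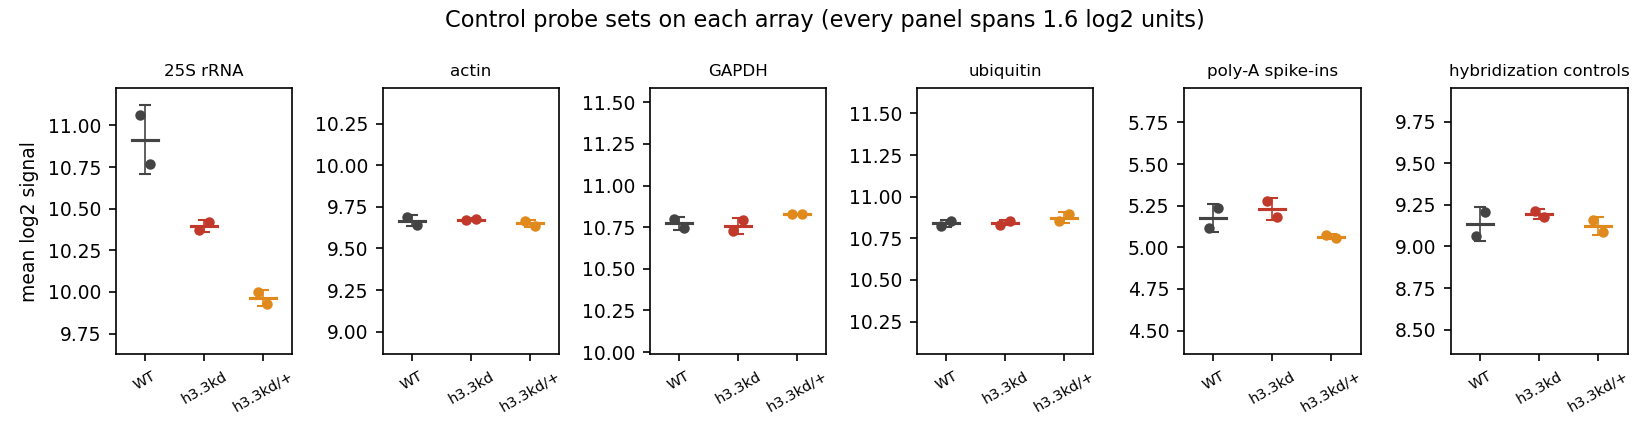
Mean log2 signal of control probe sets on each array (points), with the group mean (line) and SD (bar, n = 2) for WT, h3.3kd and h3.3kd/+. The 25S rRNA signal falls from 10.91 in WT to 10.39 in h3.3kd and 9.96 in h3.3kd/+, while actin stays between 9.64 and 9.69 on all 6 arrays.

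In h3.3kd, which combines both mutations with the artificial microRNA, 1570 of 22746 probe sets (6.90%) differed from WT, of which 1045 fell and 525 rose. Falls were also deeper: the median fall was 1.66-fold and the median rise 1.46-fold, and 281 probe sets fell against 50 that rose by at least 2-fold. The most affected probe set, 250397_at, was among the brightest on the WT arrays, above 97.3% of all probe sets, and fell 50.6-fold, from 10.21 ± 0.08 to 4.55 ± 0.29 (log2, SD, n = 2; log2 change -5.66 ± 0.16 SE, adjusted p = 2.34e-05). Whether this or another named probe set measures HTR4, HTR5 or HTR8 itself is unknown, as no probe set was paired with a gene. The probe set 247049_at fell 17.7-fold, from 7.10 ± 0.06 to 2.96 ± 0.21 (adjusted p = 2.34e-05), a level between the 23.4th and 27.5th percentiles of the h3.3kd arrays. In the other direction 265817_at rose 22.7-fold, from 3.35 ± 0.34 to 7.86 ± 0.09 (log2 change 4.50 ± 0.15 SE, adjusted p = 5.28e-05), and 264400_at rose 6.34-fold, from 4.23 ± 0.35 to 6.89 ± 0.39 (adjusted p = 0.00759).

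The 10 probe sets with the largest falls by the naming rule had log2 changes of -5.66 to -2.25 in h3.3kd. Of these, 9 were also called lower in h3.3kd/+, where the 10 changes ranged from -5.35 to -0.135. The 10 with the largest rises rose by 1.32 to 4.50. All 10 were also higher than WT in h3.3kd/+, by 0.64 to 3.49, and 6 of them were called there. Among those not called in h3.3kd/+ was 264400_at, with a change of 1.64 (adjusted p = 0.0504). Calls were distributed unevenly over the signal range, cut into 3 equal bins by the mean signal over all arrays. In the bright bin 280 fell and 232 rose, in the middle bin 588 fell and 254 rose, and in the dim bin 177 fell and 39 rose. Probe sets that can match several transcripts (suffix _s_at) changed about as often as the others, with 47 falls and 17 rises among 935 (6.84% against 6.94%). None of the 126 probe sets with the suffix _x_at, which can cross-hybridize, passed. An unadjusted p under 0.05 was reached by 5021 probe sets (22.1%), where a fraction of 0.05 would be expected without any change. In the same arrays the 25S rRNA signal was 1.43-fold lower than in WT. The number called was 312 without h3.3kd replicate 1, 617 without h3.3kd replicate 2, 462 without WT replicate 2, 1088 without WT replicate 1 and 869 without either one of the h3.3kd/+ arrays, which enter this comparison only through the variance; falls made up at least 65.5% of the calls each time. Changes of at least 2-fold numbered 201 without h3.3kd replicate 1 and 213 without WT replicate 2. The call of 264400_at was lost without WT replicate 2 (adjusted p = 0.07).

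In h3.3kd/+, 818 probe sets (3.60%) differed from WT, of which 532 fell and 286 rose. As in h3.3kd the changes of at least 2-fold were mostly falls, 129 against 33. The median fall was 1.66-fold and the median rise 1.5-fold. Again 250397_at showed the largest fall, 40.8-fold to 4.87 ± 0.25 (log2 change -5.35 ± 0.16 SE, adjusted p = 0.000105), followed under the rule by 265611_at, which fell 11.35-fold from 10.04 ± 0.28 to 6.54 ± 0.11 (adjusted p = 0.00241). The largest rise was that of 265817_at, 11.2-fold to 6.84 ± 0.03 (adjusted p = 0.000651), and the next under the rule was 246075_at, 5.19-fold from 4.1 ± 0.35 to 6.47 ± 0.08 (adjusted p = 0.00248). The 10 largest falls had log2 changes of -5.35 to -1.53. Of these probe sets, 9 were also called lower in h3.3kd, whereas 1 changed by only -0.04 there. The 10 largest rises ranged from 1.4 to 3.49 log2 units and 7 of these were also called higher in h3.3kd. The smallest change in h3.3kd among these 10 rises was 0.08. In the bright bin 117 probe sets fell and 153 rose, in the middle bin 326 fell and 117 rose, and in the dim bin 89 fell and 16 rose.

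The split between falls and rises in h3.3kd/+ changed with the scaling of the arrays. Centring each array on its median adds 0.06 log2 units to every change, although the median change was 0 as deposited, and 360 probe sets then fell and 445 rose. After quantile normalization, with a median change of 0.01, 403 fell and 330 rose. Fits with 1 array left out have 2 residual degrees of freedom and a group with a single array, so they call fewer probe sets by construction. A lower count in them is therefore not by itself a sign that the array left out was unusual. The count depended on single arrays: it was 11 without h3.3kd/+ replicate 1, 47 without h3.3kd/+ replicate 2, 33 without WT replicate 2, 308 without WT replicate 1 and 427 without either one of the h3.3kd arrays. Changes of at least 2-fold numbered 11, 47, 32, 149 and 142 in these fits, with at least 79.2% falls. The calls of 265611_at and 246075_at in h3.3kd/+ were lost without h3.3kd/+ replicate 1 (adjusted p = 0.0545 for both), whereas those of 250397_at and 265817_at held with each array left out (at most 0.00823 and 0.0279). In the same arrays the 25S rRNA signal was 1.93-fold lower than in WT. An unadjusted p under 0.05 was reached by 4679 probe sets (20.6%), where a fraction of 0.05 would be expected without any change.

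The 2 sets of changes against WT overlapped. Of the probe sets called in both mutant genotypes, 445 fell and 193 rose in both, and 0 moved in opposite directions. Independent lists of the same lengths would share 24.4 falls and 6.60 rises, a value that leaves out the shared WT arrays. The count of 0 does not cover uncalled changes. Among the probe sets with the lowest ID numbers, many lay above WT in h3.3kd and below WT in h3.3kd/+. Almost all of these were uncalled in either comparison, and they were not tested as a group. Across all probe sets, which are not independent replicates, the 2 sets of log2 fold changes correlated at r = 0.80 and had the same sign in 75.3%, against 0.54 to 0.61 and 69.4 to 70.7% in 100 simulations of unchanged groups that share the WT arrays. Their covariance was 0.0664 against a simulated mean of 0.0123. The difference of 0.0540 estimates the covariance beyond that added by the replicate noise of the shared WT arrays. A deviation that both WT arrays have in common was not simulated and would remain in this difference. Without h3.3kd/+ replicate 1 the shared calls numbered 9 falls and 2 rises, without h3.3kd/+ replicate 2 they numbered 36 and 8, and without WT replicate 2 they numbered 28 and 5, while the covariance stayed between 0.0635 and 0.0881 with any array left out. Leaving out h3.3kd replicate 1, h3.3kd replicate 2 or WT replicate 1 left 164, 238 and 215 shared falls and 41, 49 and 75 shared rises. A further 932 probe sets were called in h3.3kd and not in h3.3kd/+. Of these, 4 differed between the 2 mutant genotypes when that difference was tested, 13 at an adjusted p under 0.1 and 43 with a signal-dependent prior.

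**Figure D2:**
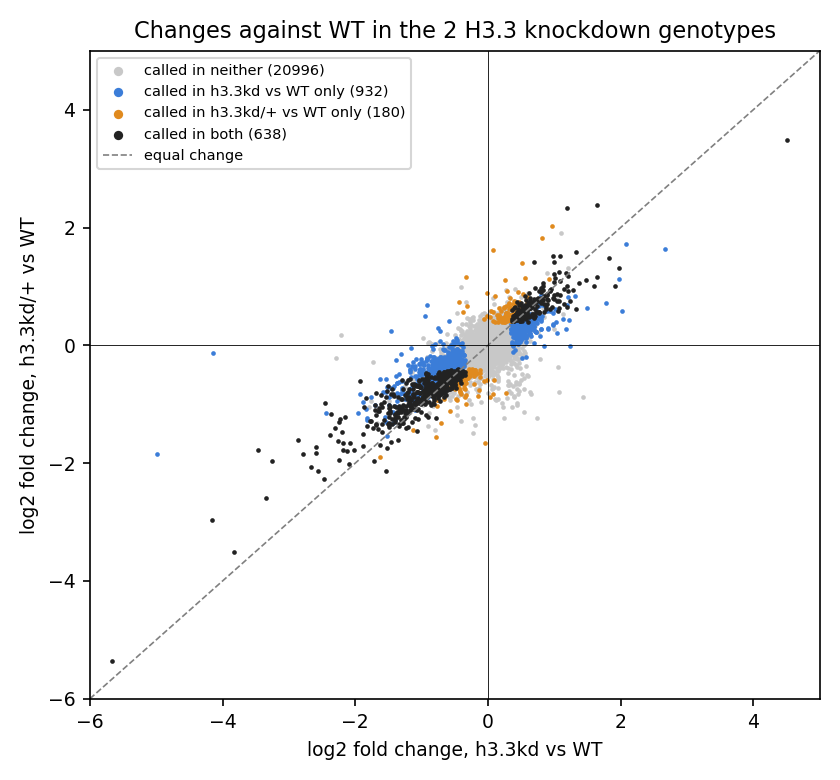
Log2 fold change of each of 22746 probe sets against WT in h3.3kd (horizontal axis) and in h3.3kd/+ (vertical axis), coloured by the comparisons in which it passed an adjusted p of 0.05; both axes use the same WT arrays. The 638 probe sets called in both lie in the lower left and upper right quadrants, and 247049_at lies apart at -4.14 in h3.3kd and -0.13 in h3.3kd/+.

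Compared directly, h3.3kd and h3.3kd/+, which by their labels differ in the artificial microRNA against HTR5, differed in 8 probe sets, 7 lower and 1 higher in h3.3kd. The count depended on the variance model and the threshold: a signal-dependent prior called 92 (66 lower and 26 higher), and an adjusted p under 0.1 called 28 (24 and 4). The probe set 247049_at was 16.1-fold lower in h3.3kd than in h3.3kd/+ (log2 change -4.01 ± 0.11 SE, adjusted p = 5.3e-05), where its level of 6.96 ± 0.04 differed from WT by -0.13 ± 0.11 SE (adjusted p = 0.552). A graded fall was seen at 245736_at, from 9.43 ± 0.31 in WT to 8.46 ± 0.09 in h3.3kd/+ and 6.98 ± 0.06 in h3.3kd, with an adjusted p of 0.0231 for h3.3kd/+ against WT and 0.0468 between the mutants. The 1 probe set that was higher in h3.3kd, 262186_at, stood at 3.13 ± 0.22 in WT, 3.72 ± 0.11 in h3.3kd/+ and 5.16 ± 0.09 in h3.3kd (adjusted p = 0.0375 between the mutants), and was named after its values were seen. Of the 7 that were lower, 3 had fallen against WT in both mutants, 3 had fallen in h3.3kd and were not called in h3.3kd/+, and 1 had risen in h3.3kd/+ and was not called in h3.3kd. Some strong falls against WT were close in size, and 250397_at differed between the mutants by -0.31 ± 0.16 SE (adjusted p = 0.623) and 265611_at by -0.32 ± 0.22 SE (adjusted p = 0.701). With 1 array left out these differences ranged from -0.515 to -0.105 at 250397_at and from -0.645 to 0.015 at 265611_at. At 265817_at, the largest rise, the change was 1.01 ± 0.15 SE larger in h3.3kd, which did not pass the test (adjusted p = 0.116) but did with a signal-dependent prior (0.0147). An unadjusted p under 0.05 between the mutants was reached by 2124 probe sets (9.34%), where a fraction of 0.05 would be expected without any change. The number called was 1 without h3.3kd replicate 1, h3.3kd replicate 2 or h3.3kd/+ replicate 2, 3 without h3.3kd/+ replicate 1 and 4 without either one of the WT arrays. The call of 247049_at held in all 6 of these fits (adjusted p at most 0.00655), that of 245736_at was lost without any 1 of the mutant arrays (up to 0.366), with the replicate block (0.06) and with the dim probe sets left out (0.0582), as was its call in h3.3kd/+ against WT without either one of the h3.3kd/+ arrays (0.168 and 0.123), and that of 262186_at in all 6 (0.0524 to 0.273).

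**Figure D3:**
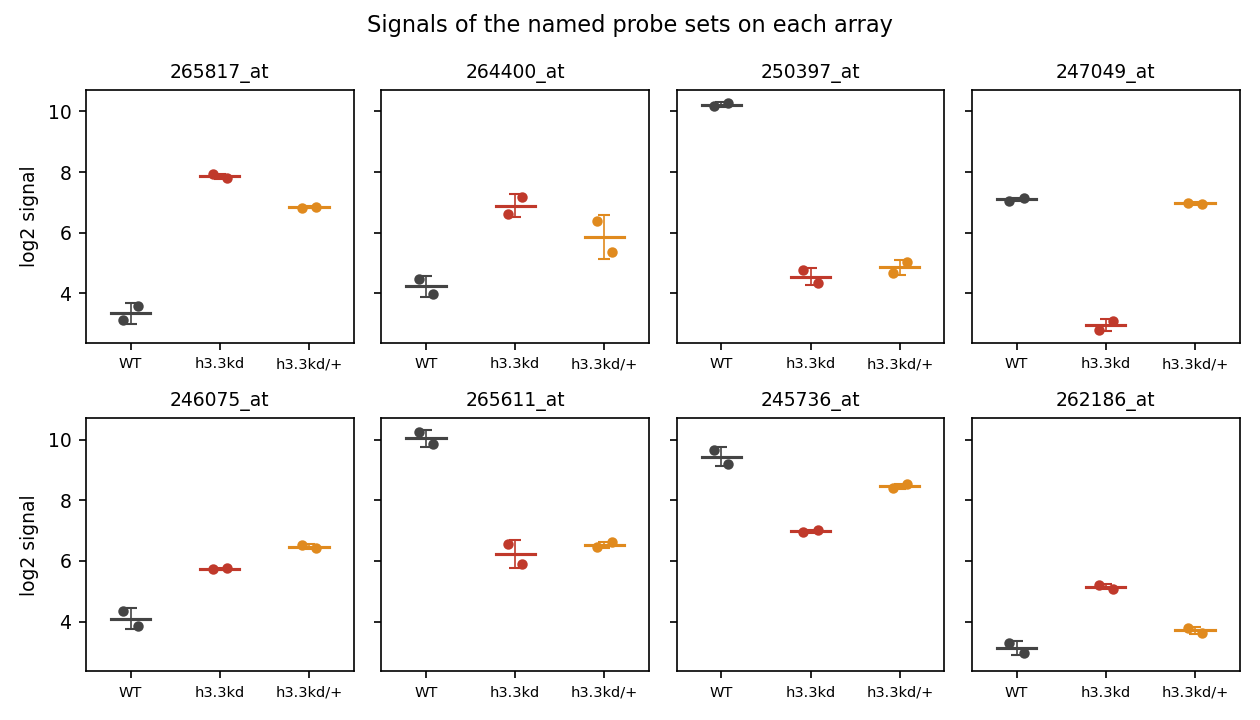
Log2 signal of the 8 named probe sets on each array (points), with the group mean (line) and SD (bar, n = 2). The probe set 247049_at is near 7 in WT and h3.3kd/+ and near 3 in h3.3kd, whereas 250397_at drops from 10.21 in WT to 4.55 and 4.87 in both mutants.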

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

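Under quantile normalization again, centring on the array median and the replicate block, the counts of called probe sets for each mutant against WT stayed within 1.5 times the main count, and the main and alternative calls shared 1443, 1403 and 1367 of 1570 probe sets in h3.3kd and 666, 646 and 682 of 818 in h3.3kd/+, in the same direction. The replicate block gave 1565, 854 and 5 calls for h3.3kd against WT, h3.3kd/+ against WT and h3.3kd against h3.3kd/+, and the replicate numbers did not pair the arrays. With the trend and robust prior the counts were 2229, 1621 and 92, and 2064 by the F test. At an adjusted p under 0.1 they were 2627, 1862, 28 and 2166. Of the 932 probe sets called in h3.3kd and not in h3.3kd/+, 43 and 13 were called between the mutants in these fits, tried after seeing the data. At a change of at least 2-fold they were 331, 162 and 6. With only the 4 arrays compared they were 869, 427 and 4, with fewer residual degrees of freedom by construction. Leaving out the dimmest 40% of probe sets gave 1586 (56.8% falls), 1069 (53.9% falls) and 4 calls, 315 shared rises against 193, and a covariance of 0.0788. Leaving out each array in turn, with the lone array assumed to vary like the other groups, gave 312 to 1088 calls for h3.3kd, 11 to 427 for h3.3kd/+, 1 to 4 between the mutants and 129 to 449 by the F test, fewer at 2 residual degrees of freedom. The lowest counts for h3.3kd, h3.3kd/+ and the F test were without h3.3kd replicate 1, h3.3kd/+ replicate 1 and WT replicate 2, and 3 fits shared the lowest between the mutants. Shared falls then ranged from 9 to 238, shared rises from 2 to 75, the covariance from 0.0635 to 0.0881, and the effect ratio from 0.695 to 0.785. Its turned value, 0.973 to 1.19, and the ratio of the SDs, 0.771 to 0.884, were added after seeing the data. The percentage of falls was 65.5 to 80.1% in h3.3kd and 71.4 to 84.8% in h3.3kd/+. Changes of at least 2-fold, whose alternatives were chosen after seeing the data, numbered 201 to 370 in h3.3kd and 11 to 149 in h3.3kd/+ when arrays were left out. Changes under 2-fold, added in the same way, numbered 1239 and 656, with the trend and robust prior 1923 and 1465, and with arrays left out 111 to 718 and 0 to 285. The percentage of falls was 65.0% in h3.3kd/+ as deposited, 44.7% after centring and 54.98% after quantile normalization; in h3.3kd it was 66.6%, 59.4% and 60.5%. Of 321 other values of named probe sets and 25S rRNA, 287 kept their side of the threshold, 26 lost a call, 8 gained one and 0 changed the direction of a call; the cause was not tested. The gene list, transposable element, gene length and per-locus alternatives were not run because no probe set could be paired with a gene, and the pseudocount alternative did not apply to log2 values.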

Other observations

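The tests of the scaling of h3.3kd/+, of the changes under 2-fold, of the signal-dependent spread, of the shared WT arrays, of 25S rRNA, of a batch and of the ratio at 247049_at were chosen after the results they bear on were seen. The others were written before the values they measure were seen, but the changes of at least 2-fold and 247049_at had been picked out from the main results by then. Over all probe sets the noise-corrected slope of the changes in h3.3kd/+ on those in h3.3kd was 0.72, the slope turned around was 1.06, and the SD of the changes, which favours neither direction, was 0.82 times as large in h3.3kd/+. When probe sets with a change of at least 2-fold were selected on 1 h3.3kd array against 1 WT array (327 to 587 probe sets) and measured against the other WT array, h3.3kd/+ showed 0.572 to 0.778 times the mean change of the other h3.3kd array. When they were selected on 1 h3.3kd/+ array instead (210 to 345 probe sets), h3.3kd showed 0.934 to 1.28 times the mean change of the other h3.3kd/+ array. Selection on h3.3kd favours a larger h3.3kd change by itself, so the splits chosen on h3.3kd decide nothing about size. In the splits chosen on h3.3kd/+, where selection works the other way, the h3.3kd change was the larger in 3 of 4. The splits reuse the same arrays and are not independent.

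Taken over all probe sets, the changes in h3.3kd/+ followed those in h3.3kd. The mostly uncalled opposite changes at the lowest ID numbers are an exception, and they were not weighed against the causes below. The covariance of 0.0664 exceeded the highest of 100 simulations with shared WT arrays, 0.0134. This argues against replicate noise in the shared WT arrays as the whole cause. The simulations hold no deviation common to both WT arrays, so they do not decide on one. A lower carry-over of ribosomal RNA in the mutant RNA stays open as a cause: it would predict larger effects where the 25S rRNA signal is lowest, and the SD of the changes in h3.3kd/+ was 0.771 to 0.884 times that in h3.3kd with any 1 array left out, but the 25S rRNA signals of the mutants were not called different (0.43, adjusted p = 0.345), and the turned slope fell to 0.973 without WT replicate 2. Handling of the WT arrays in another batch cannot be told apart from genotype, because the labels give no batch; 0 of the 18 hybridization control probe sets passed, which would not reveal a difference in growth or harvest. The 24 poly-A spike-in probe sets, whose RNAs are by design added before labelling, do not decide it. Their mean differences from WT were 0.06 in h3.3kd and -0.11 in h3.3kd/+, against a WT replicate SD of 0.08. Of them, 1 was called in h3.3kd/+ and 0 between the mutants. Between the mutants their mean difference was larger, 0.167 higher in h3.3kd, with 2 of the 24 lower. The replicate SDs were 0.066 in h3.3kd and 0.015 in h3.3kd/+. The 18 hybridization controls leaned the same way, with a mean of 0.073 and 1 lower. The biological reading that the htr4 and htr8 mutations carried by both genotypes, or a single copy of the artificial microRNA, may account for most of the shared change stays open and was not tested, as no htr4 htr8 array without the artificial microRNA was analysed here.

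More probe sets fell than rose, and the parts of this pattern fared differently. Falls of at least 2-fold outnumbered rises under every rescaling tried (at least 70.1% falls). The rescalings shifted the changes by a mean of 0.013 to 0.06 log2 units, too little to overturn changes of this size. Offsets that small do not account for the deep falls, but an earlier scaling fault could not be seen this way. In the bright bin of 3 at least 75% were falls in either mutant (67 against 13 in h3.3kd, 33 against 11 in h3.3kd/+). The exact binomial 95% interval in h3.3kd/+ was 59.7 to 86.8%. Deep falls were thus not confined to dim probe sets. This does not decide on a signal floor, because a floor understates changes of dim probe sets and the change itself helps set the bin. Among the changes under 2-fold (61.7% falls in h3.3kd and 61.4% in h3.3kd/+) the direction may be technical. In the bright bin 49.3% of 432 such changes and 37.2% of 226 were falls (exact binomial 95% intervals 44.5 to 54.1% and 30.9 to 43.8%, counting error only), so by this split their excess of falls lay in dimmer probe sets. The bins were cut on the mean over all arrays, so a fall moves a probe set towards a dimmer bin and a rise towards a brighter one. The split by itself therefore does not decide whether the direction is technical. With the dimmest 40% of probe sets left out, falls made up 56.8% and 53.9% of all calls. A spread that follows the signal left 55.8% and 51.7%, but it did so by adding more rises than falls, with 1073 and 758 small falls against 764 and 403, and decides nothing. Quantile normalization left 55.2% and 50.4%, with median changes of 0.025 and 0.0125 (0.02 and 0 as deposited), so scaling could account for the excess of small falls in h3.3kd/+ and is undecided in h3.3kd. Centring left 52.9% and 39.2%, but it adds 0.025 and 0.06 to every change and so lowers the share of falls by itself. Over all calls, large and small, the lower of the rescaled percentages was 59.4% in h3.3kd, quantile normalization left 54.98% in h3.3kd/+, the bright bin of h3.3kd held 54.7% falls, and the spread that follows the signal left 59.8% there. A candidate biological explanation, that reduced H3.3 lowers transcripts of a limited set of genes, was not tested beyond this, since the genes could not be named.

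The probe set 247049_at fell in h3.3kd and was near the WT level in h3.3kd/+. Its ratio of h3.3kd/+ to h3.3kd log2 fold change was 0.0326, and the 31 other probe sets that fell at least 4-fold in h3.3kd had ratios of 0.369 to 0.964, but as the probe set with the largest fall between the mutants it was bound to have a low ratio, so whether it is one end of the same graded response stays open. Noise in single arrays is unlikely, since the adjusted p between the mutants was at most 0.00655 with any 1 array left out. A difference between the lines at or near this gene (an insertion, a deletion or a background variant) and a response that needs the full knockdown are both possible explanations, and neither was tested. The fixed rule named this probe set, but it was picked out for weighing after its values were seen, and it is a hypothesis for follow-up and not a finding about H3.3.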
